A study of Drosophila melanogaster with 48 samples.

How the data were processed

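The samples were pools of 5 brains of 3-day-old virgin flies of line DGRP-900, dissected after 24 h of feeding on chemically defined food with dye, with 0 mM drug, 7 mM chlorpromazine, 0.5 mM trifluoperazine dihydrochloride or 60 mM sodium salicylate. Each sex and treatment had 6 replicates, and per the labels females were placed on the food 2 h ahead of males. Libraries were made from 30 ng of total RNA with 10 pg of ERCC spike-in RNA and read as 75 nt single-end stranded reads on a HiSeq 2500. Per the submitters' processing notes, reads were handled with CASAVA 1.8.2 and bcl2fastq 1.8, aligned with STAR 2.5.1b, sorted with SAMtools 1.3.1 and counted with HTSeq 0.6.1p1. The genome build and annotation used for that counting are not given in the sources used here.

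The deposited count table holds raw read counts per gene, which were used for all comparisons. It has 17371 gene rows and 96 spike-in rows, and 2160 genes have no count in any library. The deposited normalized table holds counts scaled by DESeq2 1.10.1 per the submitters' notes, a normalized signal. It was checked to equal the raw counts divided by 1 size factor per library, with a largest relative deviation of 8.6e-10, and was not used further. The deposited annotation of the spike-in sequences was not used here. Symbols were found for 17151 of the gene IDs, and 220 were kept by ID. Among 120 pairs of replicate libraries of a group, 0 were identical and the lowest chi-square per gene was 9.74.

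Gene counts ranged from 4319536 to 14289700 per library (median 8283268). Spike-ins took 0.145 to 41.3% of all counts (median 0.640%), and 117 rRNA genes took 1.94 to 31.3% of gene counts (median 6.87%). Spike-in counts stayed out of library sizes and gene tests. The biological coefficient of variation was 0.377 over the tested genes, and 0.353 with the replicate number as a block.

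Genes were tested in edgeR 4.0.16 under R 4.3.3 with TMM scaling and the quasi-likelihood F test with robust estimation, in 1 fit of the 48 libraries with a mean for each of the 8 groups. The filterByExpr function with these groups kept 9264 genes. Contrasts were each drug against control over both sexes and in each sex, the difference of the response between the sexes, chlorpromazine against trifluoperazine over both sexes, and female against male controls. Values of p were two-sided and adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05. Contrasts, tests, lists, the rule for naming genes and a first set of alternatives were chosen before the data were examined. A part of the naming rule, that a pair without a count has no sign, was set after results were seen.

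The replicate number is a day of dissection in the labels. Residuals of log2 CPM correlated by 0.0769 on average between libraries of the same day and sex, by 0.0295 between the sexes on the same day and by -0.00187 otherwise. The fit set beforehand has no block. One with the replicate number as a block is given where it changes a call or moves a count by over 1.5 times.

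The 35 gene lists were written from general knowledge of fly genes. Of the names on them 9 had no row in the count table and 22 were matched through older symbols. They are cytochrome P450, glutathione S-transferase, UDP-glycosyltransferase, ABC drug transporter, oxidative stress, heat shock, endoplasmic reticulum stress, amino acid response, antimicrobial peptide, Turandot, metallothionein, starvation and insulin, monoamine signalling, calcium signalling, activity-regulated, clock, sterol and fatty acid, lysosome, respiratory chain, ribosomal protein, proteasome, glycolysis, cell death, ion transport, neuropeptide, synapse, glia, retina, fat body, haemocyte, muscle, gut enzyme, cuticle, odorant-binding protein and sex determination genes. Lists were tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over lists and the 3 drugs. An estimated correlation and the fry test were run beside it. Member counts adjusted over the list alone use the p of the members only.

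Genes named for a drug over both sexes passed the threshold, had a mean CPM of at least 5 and the same sign in at least 10 of the 12 pairs of day and sex (a pair without a count has none), and were the 8 largest rises and 8 largest falls. For each list that was called or had at least 3 called members, up to 3 called members with the smallest adjusted p were named. Dop1R1, Dop1R2, Dop2R, DopEcR and Cam were named for both phenothiazines whatever their result. For the sex difference of each drug the 4 genes with the smallest adjusted p in each direction were named, and for the control sexes the 5 largest in each direction with a mean CPM of at least 5 and the called members of the sex determination list. Naming from lists within a sex, Ars2 under trifluoperazine, the salicylate genes of males, and the genes named for the salicylate comparison over both sexes were chosen after their values were seen. Positions are from the Ensembl annotation of assembly BDGP6.

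Spike-in shares, rRNA shares, total counts, genes detected and marker sums were compared by exact permutation over the 924 regroupings of 6 and 6 libraries, adjusted over the 6 comparisons of drug and sex. For spike-in shares an exact sign-flip test over the 64 flips of 6 days was the blocked alternative. Relations between rRNA share, spike-in share and respiratory chain transcripts used values centred within groups and 100000 permutations, adjusted over the 3 relations. Simulated unchanged groups for the overlap of the drugs were drawn 20 times against the real controls.

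Alternatives tried were relative log expression factors, library sizes from spike-ins, no filter on low counts, a filter of 5 CPM in 6 libraries, the replicate block, a fit of only the groups compared, the DESeq2 1.42.0 Wald test and each replicate number left out. Chosen after the data were seen were each single library left out, spike-ins with a pool ratio near 1 (14 of the 57 spike-ins with a mean count of at least 10), the log2 rRNA share as a covariate, removal of each library's lowess trend on exon length (span 0.3, 9123 of the tested genes with a length), the fit without gut-rich and spike-rich libraries, the limit of 1000 CPM that defines gut-rich libraries, salicylate as a reference, and list tests within a sex and on sex differences. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.

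The tests were tried on simulated data, with counts of independent genes drawn at the spread estimated for each gene. With 100 genes changed by 1 or 2 on the log2 scale, edgeR recovered 94 and 99 for both sexes and 91 and 96 in females, DESeq2 recovered 96 and 99, and edgeR called 0 with none changed. Camera, with both kinds of correlation, and fry recovered a changed glycolysis list with 0 other lists called. A changed interaction was not simulated.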

Results

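Brains of virgin Drosophila melanogaster of the inbred line DGRP-900 were profiled by stranded, single-end polyA+ RNA sequencing after 24 h on food with or without a drug. Females and males received no drug, 7 mM chlorpromazine, 0.5 mM trifluoperazine dihydrochloride or 60 mM sodium salicylate. Chlorpromazine and trifluoperazine are phenothiazine antipsychotics known as antagonists of dopamine receptors, and both bind calmodulin. Each of the 8 groups held 6 libraries, 1 for each day of dissection, and each library was a pool of 5 brains, which gives 48 libraries. Flies were kept at 25 °C in constant light, per the labels. In each library 9509 to 12314 genes had at least 1 count. Female trifluoperazine libraries held fewer gene counts than female controls (mean 6284000 ± 1526000 against 10930000 ± 1371000, SD, n = 6 each, exact permutation test, adjusted p = 0.013). Values below are CPM (counts scaled to library size) as group mean ± SD with n = 6, and fold changes are fitted log2 ratios of drug to control of the same sex ± SE.

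In brains of chlorpromazine-fed flies of both sexes, the transcript of the octopamine receptor gene Octbeta2R fell by 0.67 ± 0.13 on the log2 scale (adjusted p = 0.0292, higher in 2 of 12 pairs of the same day and sex). Octbeta2R (FBgn0038063, chromosome 3R, 12550625 to 12595725) went from 126 ± 51.1 to 76.7 ± 13.9 CPM in females and from 102 ± 28.9 to 65.7 ± 7.46 CPM in males. Among the other falls were dpr7, of a family of neuronal cell surface proteins (-0.39 ± 0.08, adjusted p = 0.0426), and Fis1, of mitochondrial fission (-0.45 ± 0.12, adjusted p = 0.0471). Maf1, a repressor of RNA polymerase III, fell by 0.32 ± 0.08 and the histone kinase gene Haspin by 0.35 ± 0.09 (adjusted p = 0.0471 for both). CG7646 fell by 0.48 ± 0.10 (adjusted p = 0.0372), CG40498 by 0.34 ± 0.07 (0.0292) and l(2)41Ab by 0.60 ± 0.14 (0.0431).

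Most rises were larger and far more uneven between libraries. The digestive alpha-amylase gene Amy-p (FBgn0000079, chromosome 2R, 17118636 to 17120303) rose by 5.31 ± 1.40 (adjusted p = 0.0492, higher in 10 of 12 pairs), from 52.3 ± 114 to 571 ± 1087 CPM in females and from 7.23 ± 5.67 to 1009 ± 1621 CPM in males. Its neighbour Amy-d rose by 4.87 ± 1.21 (adjusted p = 0.0471) but was higher in 7 of 12 pairs only. CG3906 rose by 7.24 ± 1.88, CG11672 by 6.75 ± 1.75 and CG10405 by 5.71, with an adjusted p from 0.0431 to 0.0471. Smaller rises were those of Gfat2, of the hexosamine pathway (0.26 ± 0.07, adjusted p = 0.0471), TBC1D23 (0.24 ± 0.05, 0.038) and l(1)G0320 (0.19 ± 0.05, 0.0471). Fst, a gene known for its induction during recovery from cold, also rose (adjusted p = 0.0372, higher in 11 of 12 pairs). It reached 65.8 ± 120 CPM in males, where no control held a count, so no fold is given. Of the 68 genes that rose, 66 had their highest value of all 48 libraries in 1 of the 7 libraries with over 1000 CPM of gut enzyme transcripts. Those 7 included 4 of 12 chlorpromazine libraries and 1 of 12 controls (Fisher's exact p = 0.317).

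**Figure D1:**
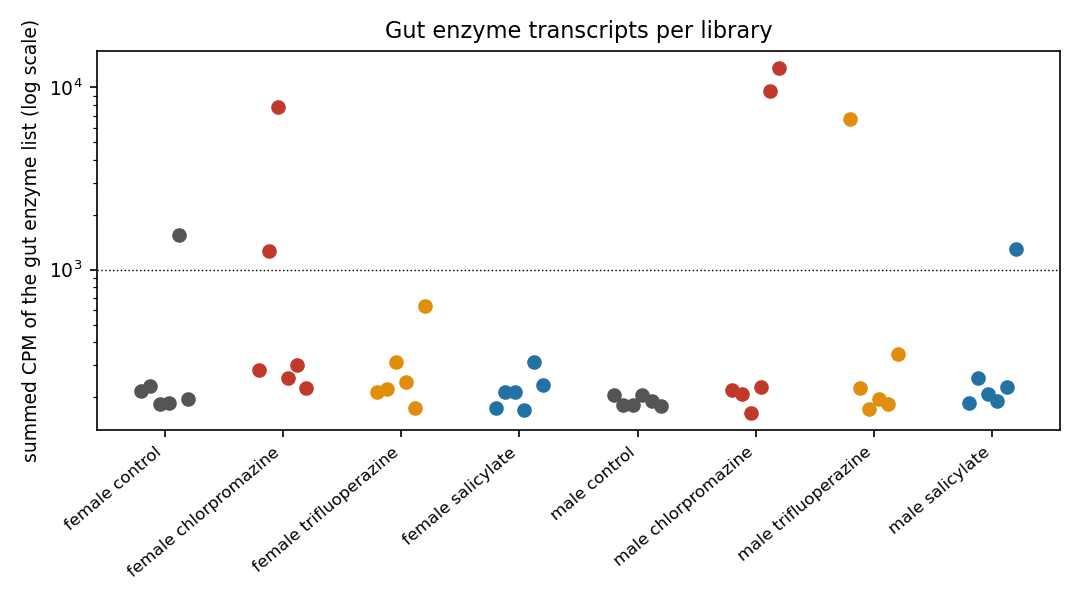
Summed CPM of the gut enzyme list in each library (points, log scale) by group, with a dotted line at 1000 CPM. The 7 libraries above the line run from 1260 CPM upwards and the others lie at or below 631 CPM.

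Among the lists fixed before the data were examined, camera with a preset correlation called 13 of 35 for chlorpromazine in both sexes, and none held with an estimated correlation (adjusted p = 0.487 to 0.777). Gut enzymes stood highest, with a median of 3.93 over 13 tested members. Of these, 2 rose over all genes and 10 adjusted over the list alone (camera adjusted p = 1.3e-07, adjusted p = 0.768 with an estimated correlation). The lists of endoplasmic reticulum stress (adjusted p = 1.0e-06), lysosome (0.00114), proteasome (0.00156), UDP-glycosyltransferase (0.0178), metallothionein (0.028), fat body markers (0.0433) and activity-regulated genes (0.0467) ranked upwards. With an estimated correlation their adjusted p was 0.487 for endoplasmic reticulum stress and metallothionein, 0.770 for lysosome and 0.777 for the other 4. Among their members, Fst of the fat body list rose over all genes, and 2 lysosome, 2 fat body and 1 metallothionein genes rose adjusted over the list alone. Dopamine, serotonin and octopamine signalling ranked downwards (median -0.12, adjusted p = 1.7e-04, 0.768 with an estimated correlation), with Octbeta2R its 1 member called over all genes and 2 that fell adjusted over the list alone. Heat shock (3.3e-04), calmodulin and calcium signalling (4.8e-04), muscle markers (0.0111) and synapse and neuron markers (0.0139) also ranked downwards, each at an adjusted p of 0.777 with an estimated correlation. Of 17 heat shock genes 9 fell adjusted over the list alone, with a median of -0.91, and the list's adjusted p was 0.849 without female control replicate 4 and 0.68, upwards, without replicate 4.

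With the replicate block the adjusted p of the activity-regulated list was 0.0554 and that of fat body markers 0.0518. The remaining lists passed no threshold. Their adjusted p was 0.0527 for cytochrome P450, 0.216 for glutathione S-transferase, 0.328 for ABC drug transporters, 0.0846 for oxidative stress, 0.0689 for the amino acid response, 0.21 for Turandot and 0.173 for starvation and insulin. It was 0.434 for the circadian clock, 0.202 for sterol and fatty acid metabolism, 0.329 for the respiratory chain, 0.106 for ribosomal protein and odorant-binding protein genes, 0.0883 for glycolysis, 0.476 for cell death, 0.886 for neuropeptides and 0.579 for cuticle. Antimicrobial peptides (0.733), ion transport (0.209), glia (0.931), retina (0.794) and haemocyte markers (0.683) and sex determination genes (0.365) had a median, a mean and a test that differed in sign.

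The 5 genes fixed in advance as targets of the phenothiazines did not pass the test, with a fold change of -0.22 ± 0.13 for Dop1R1 (adjusted p = 0.652), -0.09 ± 0.12 for Dop1R2 (0.926), -0.33 ± 0.14 for Dop2R (0.31), -0.20 ± 0.10 for DopEcR (0.483) and -0.09 ± 0.09 for the calmodulin gene Cam (0.856).

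In all, edgeR called 92 of 9264 genes (68 rose and 24 fell, 982 at unadjusted p under 0.05) and DESeq2 220. With the replicate number as a block 9 were called, of which 3 rose and 6 fell. Of the named rises Fst, CG10405 and TBC1D23 were among them, while Amy-p (adjusted p = 0.0976), Amy-d (0.121), CG3906 (0.0976), CG11672 (0.0901), Gfat2 (0.0784) and l(1)G0320 (0.0686) were not. Of the named falls Octbeta2R was (0.0426), while Fis1 (0.0784), Haspin (0.0686) and Maf1 (0.0784) were not. After each library's trend on exon length was removed, 151 were called, 88 of them shared, and Octbeta2R (-0.56 ± 0.16, adjusted p = 0.0587), Maf1 (-0.30 ± 0.12, 0.249) and l(1)G0320 (0.16 ± 0.05, 0.0779) were not among them. Without the 7 gut-rich libraries and the 1 library rich in spike-ins, the count was 0. It was also 0 without female chlorpromazine replicate 2, female control replicate 2 or 4, male chlorpromazine replicate 5 or 6, or male control replicate 1, 2 or 5, left out singly. It was 3 to 11 without female chlorpromazine replicate 3, female control replicate 1, 3 or 6, male control replicate 3, 4 or 6, or female salicylate replicate 6, and 23 to 61 without female salicylate replicate 2, 3, 4 or 5 or female trifluoperazine replicate 1, 2, 4 or 6. It was 141 without male salicylate replicate 6 or male trifluoperazine replicate 6, and 199 without female control replicate 5.

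In chlorpromazine-fed females 8 of 13 glycolysis genes rose (fry adjusted p = 0.00155) and 13 of 28 genes of dopamine, serotonin and octopamine signalling fell, with 1 that rose (0.00208), while no list held in camera with an estimated correlation. Ars2, a gene of RNA processing and small RNA pathways (FBgn0033062, chromosome 2R, 6080828 to 6085625), fell from 75.8 ± 4.94 to 41.7 ± 2.22 CPM (-0.86 ± 0.07, adjusted p = 4.7e-11). The mitochondrial phosphate carrier gene Mpcp2 (FBgn0026409, chromosome 3L, 14537651 to 14540441) rose from 1413 ± 151 to 2141 ± 230 CPM (0.60 ± 0.10, adjusted p = 8.3e-05). Ddc, whose enzyme makes dopamine and serotonin, fell by 0.80 ± 0.16 (adjusted p = 6.4e-04) and the serotonin transporter gene SerT fell by 0.69 ± 0.12 (adjusted p = 2.05e-04). The clock gene per fell by 0.65 ± 0.12 (adjusted p = 4.2e-04).

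List tests within each sex and on sex differences, and members named from them, were chosen after the data were seen. Camera with a preset correlation called 14 lists in chlorpromazine-fed females, and none held with an estimated correlation (adjusted p = 0.908 to 0.992). Fry, used below, asks whether list members move on balance one way, not whether they exceed other genes. Among the glycolysis rises were Eno (0.46 ± 0.09), PyK (0.40 ± 0.08) and Gapdh2 (0.51 ± 0.10), and 9 rose adjusted over the list alone. Of 21 endoplasmic reticulum stress genes 10 rose and 1 fell (fry adjusted p = 0.00208), with the degradation factors Der-2 (0.50 ± 0.09) and Der-1 (0.47 ± 0.11) at the front. Lysosomal genes rose in 14 of 38 cases and fell in 2 (0.00386), with Cln3 up by 1.1 ± 0.26. Of 31 proteasome genes 12 rose, and 20 adjusted over the list alone (0.0397), led by Rpn5 (0.31 ± 0.07). Respiratory chain genes rose in 19 of 65 cases, and in 31 adjusted over the list alone, with ATPsyndelta up by 0.58 ± 0.14. That list did not pass fry (0.135), while camera gave it an adjusted p of 6.4e-10 (adjusted p = 0.992 with an estimated correlation). No detoxification list passed fry. Calls there were 4 rises and 3 falls of 62 cytochrome P450 genes (0.589) and rises of 5 of 29 glutathione S-transferase genes (GstE2, 0.49 ± 0.13), 4 of 20 UDP-glycosyltransferase genes (Ugt35B1, 0.94 ± 0.20) and 5 of 19 oxidative stress genes, among them the heme oxygenase gene Ho (0.48 ± 0.12), at 0.130 to 0.161.

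Of the dopamine, serotonin and octopamine genes 15 fell adjusted over the list alone. All 4 dopamine receptor genes fell in females, namely Dop1R1 (-0.58, adjusted p = 0.0258), Dop1R2 (-0.47, 0.0429), Dop2R (-0.56, 0.0364) and DopEcR (-0.53, 0.00721). Of 23 calcium signalling genes 11 fell (fry adjusted p = 0.00729), including the calcium channel genes Ca-alpha1T (-1.32 ± 0.27) and Ca-alpha1D (-1.21 ± 0.25) and the phosphodiesterase gene dnc (-0.68 ± 0.14). Of 12 clock genes 5 fell and 2 rose (0.0157), with Pdp1 at -0.63 ± 0.13 and tim at -0.47 ± 0.14. Of 18 sex determination genes 6 fell (0.00386), among them Sxl (-0.77 ± 0.18) and the dosage compensation RNA roX1, which is scarce in females (-1.09 ± 0.21). Of 21 synapse genes 7 fell, with Rim at -1.06 ± 0.22 (0.13), and the potassium channel genes Sh (-1.35 ± 0.27) and eag (-1.08 ± 0.25) fell as well. Of 17 heat shock genes 9 fell (0.709), such as Hsp70Bbb (-5.20 ± 1.23). This rested on female control replicate 4, which held 144 CPM of Hsp70Bbb against at most 2.30 in the other female controls and 29628 CPM of the list against at most 3826, and without it Hsp70Bbb was at -0.58 (adjusted p = 0.669).

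In females on chlorpromazine edgeR called 2035 of 9264 genes (923 rose and 1112 fell) and DESeq2 2255. Across genes the fold changes ran with exon length (Spearman -0.577, genes not being independent replicates), long transcripts being lower. After each library's trend on exon length was removed 974 genes were called, 687 of them shared with the first count. Glycolysis then held 8 rises and the respiratory chain 15, whereas falls of clock genes went from 5 to 1 and of monoamine genes from 13 to 5, and tim stood at 0.00 (adjusted p = 1). Rises went from 12 to 3 for proteasome, 14 to 5 for lysosome, 10 to 5 for endoplasmic reticulum stress and 5 to 0 for glutathione S-transferase genes. Falls went from 11 to 5 for calcium signalling, 7 to 3 for synapse and 6 to 2 for sex determination genes. Dop1R1 turned to 0.17 (adjusted p = 0.143), and Dop1R2, Dop2R, dnc, Pdp1, Sxl, Sh, Der-1, Rpn5, GstE2 and Ho were no longer called. The share of rRNA reads was 8.71 ± 4.00% against 6.01 ± 3.32% in the controls (exact permutation, adjusted p = 0.288). The count was 1236 without female chlorpromazine replicate 2, 1227 without female control replicate 3 and 3135 without male trifluoperazine replicate 6.

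Chlorpromazine-fed males showed opposite changes in several of these groups. Mpcp2 fell by 0.50 ± 0.10 (1751 ± 91.8 CPM in this group, adjusted p = 0.00514), where male controls 1 and 2 held 1739 and 1828 CPM and controls 3 to 6 held 2676 to 2999, and Ars2 rose by 0.40 ± 0.07 (56.6 ± 8.27 to 74.9 ± 2.49 CPM, adjusted p = 0.00514). Of 13 glycolysis genes 5 fell, among them Eno (-0.39 ± 0.09) and Gapdh2 (-0.40 ± 0.10), and 8 adjusted over the list alone (fry adjusted p = 0.0435, adjusted p = 0.938 with an estimated correlation). Respiratory chain genes fell in 12 of 65 cases and in 59 adjusted over the list alone, with ATPsyndelta at -0.63 ± 0.14 (fry adjusted p = 0.0702, camera 7.5e-20, adjusted p = 0.908 with an estimated correlation). Of 22 glia markers 3 fell, rumpel (-0.62 ± 0.12), nrv2 (-0.45 ± 0.11) and zyd (-0.35 ± 0.11), and 5 adjusted over the list alone (fry adjusted p = 0.0302, adjusted p = 0.908 with an estimated correlation). With the block zyd was at 0.053. GstE2 fell by 0.67 ± 0.13 and the vacuolar proton pump gene Vha36-1 fell by 0.39 ± 0.10. Gut enzymes rose in 10 of 13 cases, and in 12 adjusted over the list alone, with the maltase gene Mal-A6 at 7.68 ± 1.83 (fry adjusted p = 0.366, camera 0.00616, adjusted p = 0.992 with an estimated correlation). The gut-rich libraries of this group, replicates 5 and 6, held 9532 and 12784 CPM of gut enzymes. Octbeta2R fell by 0.64 ± 0.18 (adjusted p = 0.0374), whereas the 4 dopamine receptor genes did not pass the test in males.

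In males edgeR called 544 genes (150 rose and 394 fell) and DESeq2 846, and the fold changes ran with exon length in the other direction (Spearman 0.59). After removal of the length trend 122 were called, 98 of them shared. Falls then went from 12 to 5 in the respiratory chain and 5 to 3 in glycolysis and stayed at 3 in glia markers, gut enzyme rises went from 10 to 3, and Ars2 (adjusted p = 0.0674), Gapdh2, GstE2 and Vha36-1 were no longer called. The share of rRNA reads was 3.87 ± 1.57% against 14.6 ± 8.73% in male controls (exact permutation, adjusted p = 0.013), and with the log2 rRNA share as a covariate 0 genes were called by edgeR. Left out singly, male chlorpromazine replicates 1, 3, 5 and 6 gave counts of 330, 338, 165 and 236, and male control replicates 1 to 6 gave 1091, 1431, 221, 150, 30 and 173. Without replicate 5 of the controls Eno, Gapdh2, ATPsyndelta, nrv2, zyd, Vha36-1 and Mal-A6 were not called. Without male trifluoperazine replicate 6 the count was 1806.

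In the direct test of the sex difference in the response to chlorpromazine, Ars2 differed by -1.27 ± 0.10 (female minus male, adjusted p = 1.2e-11), Mpcp2 by 1.1 ± 0.14 (2.2e-06), the glycolysis gene Eno by 0.84 ± 0.12 and the kinase gene Pitslre by -1.61 ± 0.21. Ddc differed by -1.13 ± 0.23 (adjusted p = 3.2e-04), tim by -0.65 ± 0.20 (0.00925), Dop1R2 by -0.77 (0.0125), Dop1R1 by -0.73 (0.0318) and DopEcR by -0.66 (0.00886). For Dop2R the difference was -0.45 (adjusted p = 0.202) and for Octbeta2R -0.08 (interval -0.59 to 0.43, adjusted p = 0.842). In the respiratory chain 61 of 65 genes differed, 64 adjusted over the list alone, all more positive in females (fry adjusted p = 0.00503). Other lists more positive in females that passed fry were proteasome (19 of 31, 0.0121), lysosome (15 against 2 of 38, 0.00316), glia markers (11 against 1 of 22, 0.00161) and glycolysis (9 against 1 of 13, 1.5e-04). Ribosomal protein genes (18 of 80) and cytochrome P450 genes (13 against 3 of 62) did not pass fry (0.155 and 0.552). Monoamine signalling (12 against 1 of 28, 0.00293), calcium signalling (11 against 2 of 23, 0.00428) and sex determination genes (6 of 18, 3.6e-04) were more negative in females. No list held in camera with an estimated correlation (adjusted p = 0.861 to 0.969).

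**Figure D2:**
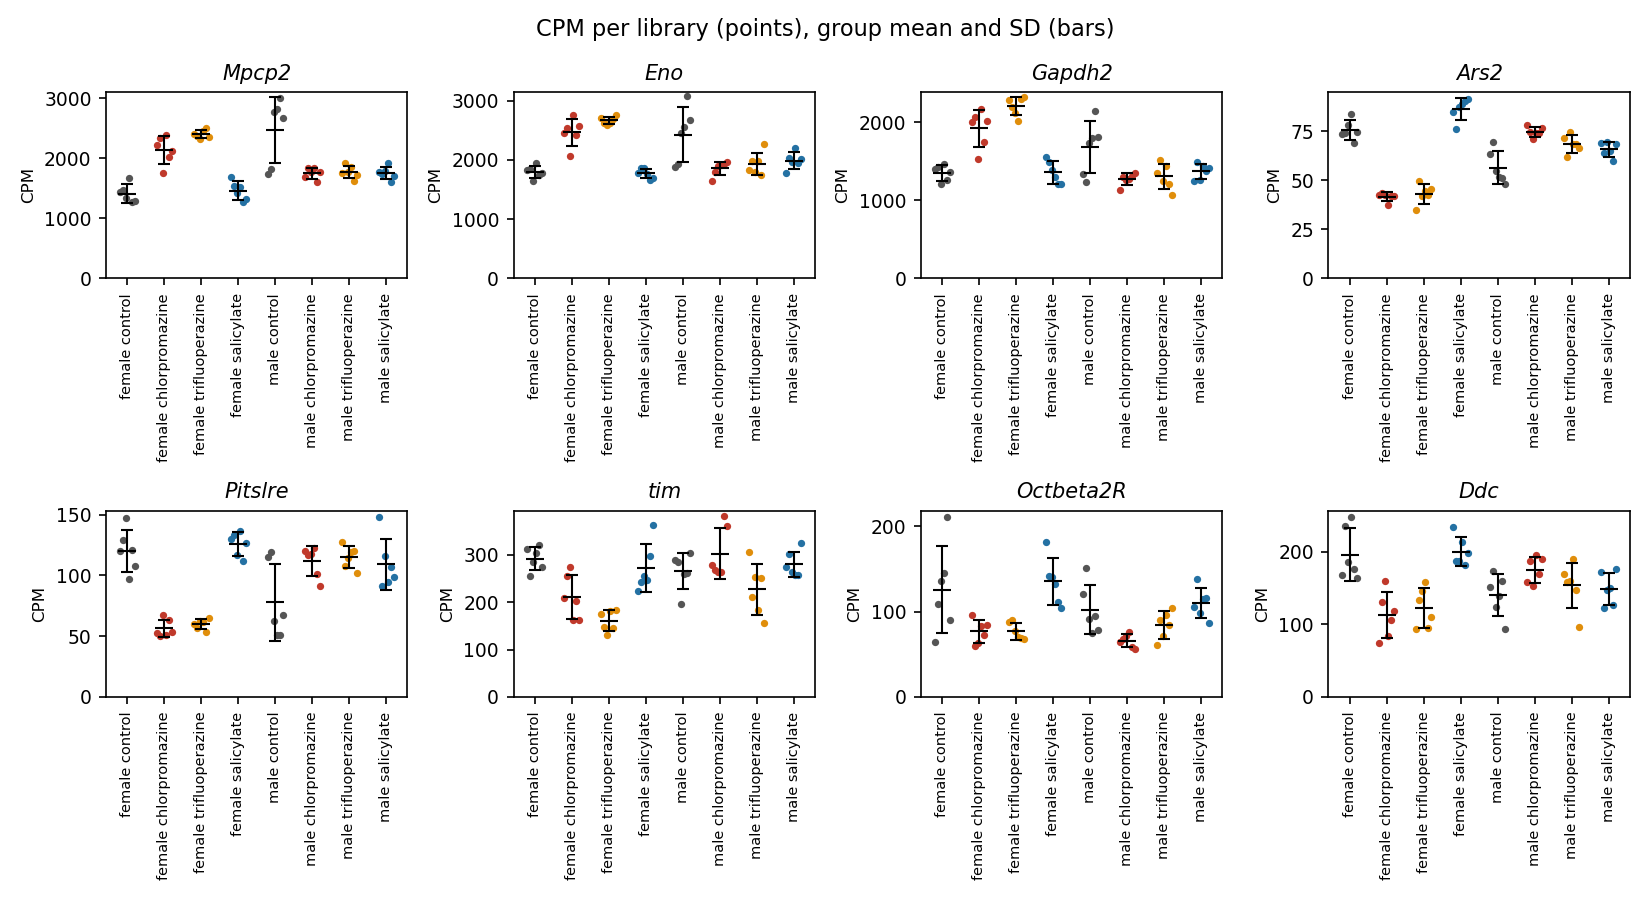
CPM of 8 named genes in each library (points) with group mean and SD (bars), 6 libraries per group. Ars2 is lower in phenothiazine-fed females and higher in chlorpromazine-fed males, and Mpcp2 shows the reverse.

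The sex difference for chlorpromazine covered 3319 genes (1805 more positive and 1514 more negative in females, DESeq2 3428). Genes more positive in females had a median exon length of 1335 nt and the others 5642 nt. Removing the length trend left 1153, of which 867 were shared, and the rRNA covariate left 345. After removal of the trend the more positive genes went from 61 to 44 in the respiratory chain, 19 to 1 in proteasome, 15 to 6 in lysosome and 11 to 9 in glia markers and stayed at 9 in glycolysis. The more negative ones went from 12 to 5 in monoamine signalling, 11 to 4 in calcium signalling and 6 to 1 in sex determination. Dop1R1 turned from -0.73 to 0.47 (adjusted p = 0.00256) and tim to 0.14 (0.745), and Dop1R2 and DopEcR were no longer called. Of the genes called in each sex, 240 went in opposite directions and 9 in the same, where chance would give 57.3 and 62.2 if genes were independent. Over all 9264 tested genes, which are not independent replicates, the fold changes of the sexes correlated by 0.357 (Pearson) and -0.453 (Spearman).

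With trifluoperazine averaged over both sexes, 2 genes passed the test and both fell. The clock gene tim (FBgn0014396, chromosome 2L, 3493986 to 3508119) fell by 0.55 ± 0.10 (adjusted p = 0.0167, higher in 2 of 12 pairs), from 292 ± 24.6 to 161 ± 22.1 CPM in females and from 266 ± 38.4 to 227 ± 54.1 CPM in males. The male difference by itself was -0.23 ± 0.14 (adjusted p = 0.412). Ars2 fell by 0.27 ± 0.05 (adjusted p = 0.0274), a mean over opposite changes in the sexes. Under the block both kept their call (adjusted p = 0.0319 and 0.0485). After removal of the length trend neither did, at -0.42 ± 0.11 for tim (adjusted p = 0.105) and -0.21 ± 0.06 for Ars2 (0.108), and 2 other genes were called. The fold change was -0.31 ± 0.14 for Dop1R1 (adjusted p = 0.278), -0.17 ± 0.12 for Dop1R2 (0.491), -0.25 ± 0.14 for Dop2R (0.37), -0.11 ± 0.10 for DopEcR (0.602) and -0.18 ± 0.09 for Cam (0.347).

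The clock list ranked downwards for trifluoperazine in both camera and fry, with 1 of 12 members called over all genes and 4 that fell adjusted over the list alone (camera adjusted p = 8.9e-04, fry 0.0257, adjusted p = 0.395 with an estimated correlation). Camera called 13 further lists. Respiratory chain (median 0.35, adjusted p = 3.6e-14), ribosomal protein (0.41, 7.4e-13), proteasome (0.19, 1.3e-11), glycolysis (5.8e-04), gut enzyme (0.00929), oxidative stress and endoplasmic reticulum stress genes (0.0292 for both) ranked upwards. Their adjusted p was 0.770 to 0.777 with an estimated correlation. Without male trifluoperazine replicate 6, whose mean log2 CPM of the respiratory chain list was 9.92 against 7.70 to 8.21 in the other 5, the respiratory chain had an adjusted p of 8.8e-04, ribosomal protein 0.188 and oxidative stress 0.206. No member was called over all genes, and 13 proteasome and 2 glycolysis genes rose adjusted over the list alone. Calcium signalling (1.8e-06), monoamine signalling (8.8e-04), synapse markers (0.00198), sex determination (0.00874), ion transport (0.0339) and haemocyte markers (0.0398) ranked downwards, at 0.487 to 0.777 with an estimated correlation. Without that library synapse markers (0.111), ion transport (0.206) and haemocyte markers (0.064) were not called, and 9 of the 14 lists were shared. Adjusted over the list alone, 1 monoamine and 4 sex determination genes fell. The other lists passed no threshold. Their adjusted p was 0.903 for cytochrome P450 and heat shock (9.1e-05, upwards, without female control replicate 4 for the latter), 0.0616 for glutathione S-transferase, 0.332 for ABC drug transporters and cell death, 0.485 for the amino acid response, 0.317 for Turandot, 0.245 for starvation and insulin, 0.146 for activity-regulated genes, 0.522 for sterol and fatty acid metabolism and 0.361 for lysosome. It was 0.939 for glia, 0.271 for retina and 0.137 for muscle markers. A median, a mean and a test that differed in sign were found for UDP-glycosyltransferase (0.94), antimicrobial peptides (0.365), metallothionein (0.931), neuropeptides (0.978), fat body markers (0.115), cuticle (0.613) and odorant-binding proteins (0.893), of which 2 of the last list rose adjusted over the list alone.

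For trifluoperazine in both sexes 1428 genes had an unadjusted p under 0.05, DESeq2 called 27 and the replicate block 6. The count was 0 without female trifluoperazine replicate 5. It was 1 without female control replicate 3, female trifluoperazine replicate 1, male control replicate 1 or 2, or male trifluoperazine replicate 5. It was 4 or 5 without female control replicate 6, female salicylate replicate 6, female trifluoperazine replicate 3 or 6, male control replicate 5, male salicylate replicate 1, or male trifluoperazine replicate 2 or 3, and 8 without female chlorpromazine replicate 1 and 11 without female trifluoperazine replicate 4.

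In trifluoperazine-fed females the clock genes vri (-0.99 ± 0.16), tim (-0.86 ± 0.14) and per (-0.77 ± 0.12) fell, each at an adjusted p from 4.7e-05 to 5.2e-05. They stood among 6 of 12 clock genes that fell, with 1 that rose (fry adjusted p = 2.2e-04). Camera called 15 lists in this group and none with an estimated correlation (adjusted p = 0.730 to 0.992, with 0.730 for clock and glycolysis and 0.908 for glia). Glycolysis transcripts rose in 9 of 13 cases (1.2e-04), with PyK at 0.59 ± 0.08 (adjusted p = 3.2e-06) and Gapdh2 at 0.71 ± 0.10 (adjusted p = 8.6e-06). Glia markers rose in 9 of 22 cases (0.00155), led by the sodium pump subunit gene nrv2 (0.67 ± 0.11), the glutamine synthetase gene Gs2 (0.69 ± 0.15) and ebony (e, 1.28 ± 0.25), whose enzyme couples beta-alanine to biogenic amines. Ars2 fell to 43.2 ± 4.93 CPM (-0.81 ± 0.07, adjusted p = 3.7e-10).

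Respiratory chain genes rose in 25 of 65 cases and in 39 adjusted over the list alone, with ATPsynbeta at 0.62 ± 0.09 (fry adjusted p = 0.065, camera 5.1e-14, adjusted p = 0.992 with an estimated correlation). Proteasome genes rose in 13 of 31 cases (fry adjusted p = 0.0337), lysosomal genes in 12 of 38 with 2 falls (0.0225) and endoplasmic reticulum stress genes in 6 of 21 (0.0113). Detoxification genes that rose were 9 of 62 cytochrome P450 genes, such as Cyp4g15 (0.86 ± 0.15) with 2 that fell, 5 glutathione S-transferase genes (GstE2, 0.65 ± 0.13), 4 of 20 UDP-glycosyltransferase genes and 4 of 19 oxidative stress genes, among them Ho (0.65 ± 0.12). Those 4 lists had a fry adjusted p of 0.751, 0.184, 0.599 and 0.203. Falls took in 11 of 23 calcium signalling genes with 1 rise (0.0196), among them the synaptic calcium channel gene cac (-1.12 ± 0.22), and 11 of 28 monoamine genes with 1 rise (0.0162), among them Ddc (-0.68 ± 0.16) and SerT (-0.51 ± 0.12). Synapse markers fell in 6 of 21 cases and rose in 1 (0.366), with the active zone gene brp at -0.80 ± 0.22. Of 18 sex determination genes 6 fell (0.00155). Dop1R1 (-0.63, adjusted p = 0.0162), Dop1R2 (-0.52, 0.0277) and Dop2R (-0.60, 0.0261) fell, and DopEcR was at -0.34 (0.0821).

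In females on trifluoperazine edgeR called 1838 genes (895 rose and 943 fell) and DESeq2 1985, and no single library moved the count by over 1.5 times. Fold changes ran with exon length (Spearman -0.462). After removal of that trend 1238 genes were called, 843 of them shared, with 36 respiratory chain and 10 glycolysis and glia genes each among the rises and 3 clock genes among the falls, down from 6. Rises went from 13 to 5 for proteasome, 12 to 10 for lysosome, 6 to 2 for endoplasmic reticulum stress, 9 to 5 for cytochrome P450, 5 to 2 for glutathione S-transferase, 4 to 2 for UDP-glycosyltransferase and 4 to 3 for oxidative stress genes. Falls went from 11 to 3 for monoamine, 11 to 6 for calcium signalling and 6 to 4 for sex determination genes, and synapse markers went from 1 rise and 6 falls to 5 rises and 3 falls. Dop1R1 turned to 0.09 (adjusted p = 0.495), and Dop1R2, Dop2R, GstE2 and brp were no longer called. The share of rRNA reads was 10.4 ± 2.88% against 6.01 ± 3.32% in controls (exact permutation, adjusted p = 0.0606), and the rRNA covariate gave a count of 1089.

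In trifluoperazine-fed males 3 of 22 glia markers fell, namely the blood-brain barrier genes moody (-0.53 ± 0.12, adjusted p = 0.0229) and Mdr65 (-0.81 ± 0.20, adjusted p = 0.0366, 0.0513 with the block) and nrv2 (-0.47 ± 0.11), and 9 adjusted over the list alone (fry adjusted p = 0.00155, camera 3.0e-07, adjusted p = 0.397 with an estimated correlation). Mpcp2 fell by 0.48 ± 0.10 (adjusted p = 0.0164) against the same divided controls. Ars2 was at 0.28 ± 0.07 (adjusted p = 0.0574) and Eno at -0.33 ± 0.09 (adjusted p = 0.0569). Of 13 glycolysis genes 4 fell adjusted over the list alone and none over all genes (fry adjusted p = 0.135). In all, edgeR called 62 genes (14 rose and 48 fell) and DESeq2 140. After removal of the length trend edgeR called 68, 45 of them shared, and nrv2 was not among them (adjusted p = 0.061). The count was 0 without the gut-rich and spike-rich libraries, 387 with the rRNA covariate, of which 274 rose and 113 fell, and 4 with the rRNA covariate and the block. Left out singly, male control replicates 1 to 6 gave 199, 220, 26, 0, 0 and 20, and male trifluoperazine replicates 1, 2, 3 and 5 gave 40, 124, 41 and 36. Without replicate 6 of that group moody (adjusted p = 0.0542) and Mdr65 (0.0743) were not called.

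For trifluoperazine Mpcp2 differed by 1.24 ± 0.14 (female minus male, adjusted p = 1.2e-07), Gapdh2 by 1.07 ± 0.14, Ars2 by -1.09 ± 0.10 (1.7e-09), Pitslre by -1.57 ± 0.21, the splicing factor gene SF1 by -1.21 ± 0.16 and Xe7 by -1.66 ± 0.22. Glia markers differed in 11 of 22 cases, 12 adjusted over the list alone (fry adjusted p = 9.9e-06), glycolysis in 8 against 1 of 13 (3.3e-05) and lysosome in 13 against 1 of 38 (0.00293), more positive in females. Clock genes (4 against 1 of 12, 0.00388) and monoamine genes (8 against 1 of 28, 0.0429) were more negative in females. None of the lists held in camera with an estimated correlation (adjusted p = 0.460 for glia and 0.663 for glycolysis). Among named genes tim differed by -0.63 ± 0.20 (adjusted p = 0.0181), Ddc by -0.81 ± 0.23 (0.00816) and Dop1R2 by -0.70 (0.0358), with Dop1R1 at -0.63 (0.0906) and Dop2R at -0.70 (0.0681). The count was 1916 (957 more positive and 959 more negative in females, DESeq2 2035), and 3184 without male trifluoperazine replicate 6. It was 1522 after removal of the length trend, 1067 of them shared. Glia then held 11 and glycolysis 8 of the more positive genes, lysosome went from 13 to 10, and the more negative clock genes went from 4 to 1 and monoamine genes from 8 to 4. For tim it was -0.10 (adjusted p = 0.819), and Dop1R2 was no longer called. Genes called in both sexes numbered 43, all in opposite directions, and over all tested genes the sexes correlated by -0.224 (Pearson) and -0.288 (Spearman).

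**Figure D3:**
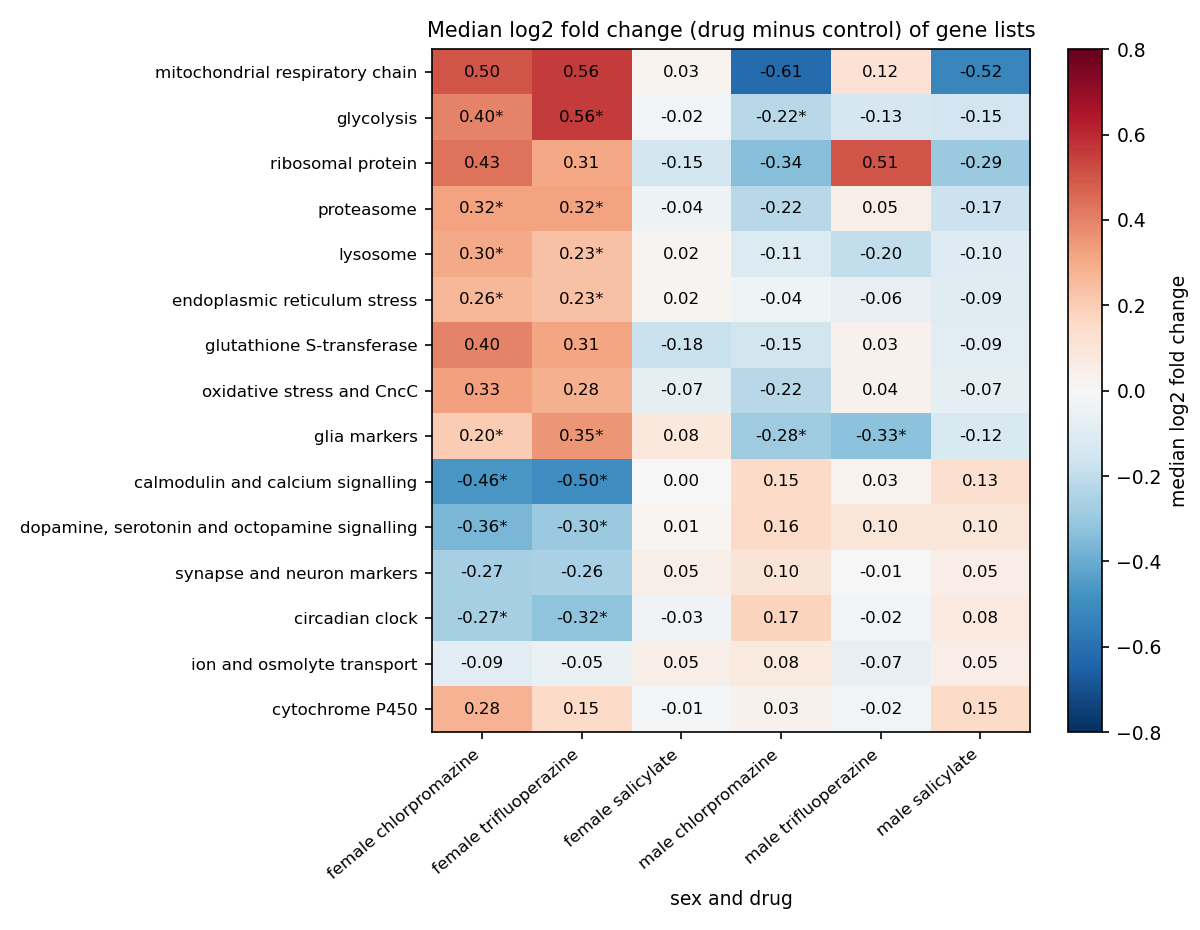
Median log2 fold change (colour) of gene lists, in rows, for each drug against control in each sex, in columns, where an asterisk marks a fry adjusted p under 0.05. The respiratory chain has a median of 0.50 in females and -0.61 in males under chlorpromazine.

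Under salicylate no gene passed the test over both sexes. The small chaperone gene Hsp26 was at -2.92 and Ars2 at 0.21 ± 0.05 (adjusted p = 0.714 for both). In males Mpcp2 fell by 0.49 ± 0.10 (1757 ± 102 CPM in this group, near male controls 1 and 2 and below the others, adjusted p = 0.0467) and CG10514 fell by 0.80. The heat shock list ranked downwards in both sexes together, with a median of -1.15 and 12 of 17 members falling adjusted over the list alone (camera adjusted p = 1.9e-09, adjusted p = 0.768 with an estimated correlation). Without female control replicate 4 it was still called (adjusted p = 0.0109). Respiratory chain (median -0.24, adjusted p = 1.1e-14), ribosomal protein (-0.22, 5.3e-12), glycolysis (-0.13, 2.9e-04), proteasome (-0.10, 3.3e-04) and glutathione S-transferase genes (-0.14, 0.0297) ranked downwards too. Starvation and insulin response (0.15, 0.00929), antimicrobial peptides (0.10, 0.0292), fat body markers (0.40, 0.0292), synapse markers (0.04, 0.0398) and calcium signalling (0.05, 0.0458) ranked upwards. For these 10 lists the adjusted p was 0.768 to 0.777 with an estimated correlation. Fat body markers were at 0.0815 with the block, the antimicrobial list turned downwards without replicate 6 (0.775), and the synapse list turned downwards with the rRNA covariate (0.515).

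The adjusted p of the remaining lists under salicylate was 0.0647 for monoamine signalling, 0.0846 for sex determination, 0.0883 for neuropeptides, 0.107 for oxidative stress and 0.106 for sterol and fatty acid metabolism, muscle markers and gut enzymes. It was 0.139 to 0.496 for ion transport, activity-regulated, UDP-glycosyltransferase, lysosome, ABC drug transporter, cytochrome P450, retina, metallothionein and odorant-binding protein lists. For endoplasmic reticulum stress, haemocyte, cell death and cuticle lists it was 0.522 to 0.94. The amino acid response (0.903), Turandot (0.94), clock (0.522) and glia lists (0.964) had a median, a mean and a test that differed in sign. Within the sexes, heat shock (camera adjusted p = 1.0e-10) and muscle markers (4.9e-11) ranked downwards in females, and the respiratory chain ranked downwards in males (1.3e-20), where 12 of 65 members fell adjusted over the list alone and none over all genes. With an estimated correlation the adjusted p was 0.908 for these 3.

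By edgeR 0 genes were called for salicylate in both sexes (463 at unadjusted p under 0.05, DESeq2 12), 0 in females (329, DESeq2 20), 2 in males (1327, DESeq2 26) and 0 for the sex difference (993, DESeq2 56). Without male trifluoperazine replicate 6 the count over both sexes was 1 and that in males 246. The male count was 95 without male control replicate 1, 171 without male control replicate 2 and 1 without female salicylate replicate 2. It was 0 without any other library, except female chlorpromazine replicates 3 and 4, female control replicate 5, female salicylate replicate 1 and male salicylate replicates 2 and 4, without which it was 2 or 3. The sex difference reached 1 to 7 genes without female salicylate replicate 2, male salicylate replicate 4, female control replicate 1, male control replicate 1 or 2, male trifluoperazine replicate 6 or female trifluoperazine replicate 5.

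The doses of chlorpromazine and trifluoperazine differed (7 and 0.5 mM), so their values stand side by side without matching of dose. No gene differed between the drugs over both sexes by edgeR (1425 at unadjusted p under 0.05, DESeq2 13). For tim the difference was 0.40 (chlorpromazine minus trifluoperazine, 95% interval 0.21 to 0.60, adjusted p = 0.233), with fold changes of -0.14 and -0.55. It was -0.18 for Octbeta2R (-0.44 to 0.07), 0.10 for Dop1R1 (-0.17 to 0.36), 0.09 for Dop1R2 (-0.15 to 0.32), -0.08 for Dop2R (-0.35 to 0.19), -0.09 for DopEcR (-0.28 to 0.11), 0.08 for Cam (-0.10 to 0.27) and 0.04 for Ars2 (-0.06 to 0.14). As a group, respiratory chain genes ranked lower under chlorpromazine, with a median difference of -0.38 and 49 of 65 lower adjusted over the list alone but none over all genes (camera adjusted p = 9.8e-21, adjusted p = 0.512 with an estimated correlation). The median difference was -0.06 in females and -0.71 in males, where the trifluoperazine group holds replicate 6 with the list mean of 9.92 given above. Camera called 17 lists in this comparison, among them activity-regulated genes (4.3e-04) and clock genes (0.00988) higher and heat shock (6.0e-04) lower under chlorpromazine, at 0.512, 0.422 and 0.593 with an estimated correlation. In females 0 genes differed between the drugs (621 at unadjusted p under 0.05), and in males 255, 249 of them lower under chlorpromazine, a count of 0 without male trifluoperazine replicate 6. The count over both sexes was 161 without male trifluoperazine replicate 1 and 1 without replicate 2, 3, 4 or 5 of that group.

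In females 1337 genes were called for both phenothiazines, all in the same direction. Ars2, Mpcp2, Eno, PyK, Gapdh2, per, tim, Ddc and SerT are among them. Independent genes would give 202 by chance and, simulated unchanged against the same controls, 0. Fold changes correlated by 0.496 across genes, against 0.0968 simulated. These references hold no trends shared across genes. With controls divided, days 1 to 3 for 1 drug and 4 to 6 for the other, 516 and 564 genes were shared in the same direction (correlation 0.061 and 0.458). In males 43 genes were shared in the same direction, Mpcp2 and nrv2 among them, with a correlation of 0.782. With divided controls it was 0.628 and 0.555, and 1 drug called 0 genes each time. Over both sexes the overlap was 1 gene, Ars2, and 0 with the block.

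Female and male control brains differed in genes known to be sex-specific. The dosage compensation RNAs roX2 (-7.46 ± 0.29, female minus male, adjusted p = 8.8e-24) and roX1 (-5.94 ± 0.24, adjusted p = 4.9e-23) and msl-2 (-1.05 ± 0.16) were lower in females. The yolk protein genes Yp2 (8.43 ± 0.88), Yp1 (8.28 ± 0.84) and Yp3 (7.82 ± 0.79), products of the female fat body, were higher, as were the odorant-binding protein gene Obp99a (6.26 ± 0.68) and the antisense RNA CR45601 (6.21 ± 0.78). Sxl (0.55 ± 0.18), tra (0.51 ± 0.16) and fru (0.96 ± 0.23) were higher in females, which makes 6 higher and 3 lower of 18 sex determination genes. Without female control replicate 4 Sxl (adjusted p = 0.0724) and tra (0.178) were not called, nor was Sxl without male control replicate 5 (0.134). The camera direction of that list was downwards (adjusted p = 0.0315) although its median was 0.06 and its mean 0.66. The transcripts lcs (-9.35 ± 1.79, 394 ± 606 CPM in males), whe, CG16826 and CG34212 were lower in females and very uneven between male controls. Fat body markers were higher in 8 of 22 cases and lower in 1 (fry adjusted p = 0.00308). Respiratory chain genes were lower in females in 44 of 65 cases, 58 adjusted over the list alone (0.0113), and glycolysis genes in 7 of 13 (0.0113). Starvation and insulin genes were higher in 3 of 17 cases, 7 adjusted over the list alone (0.00561). No list held in camera with an estimated correlation (adjusted p = 0.484 to 0.823). In all 1246 genes differed (455 higher and 791 lower in females, DESeq2 1496). The count was 798 without female control replicate 5, 708, 744, 593 and 730 without male control replicates 3 to 6, 2222 without male trifluoperazine replicate 6, and 729 with the rRNA covariate.

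**Figure D4:**
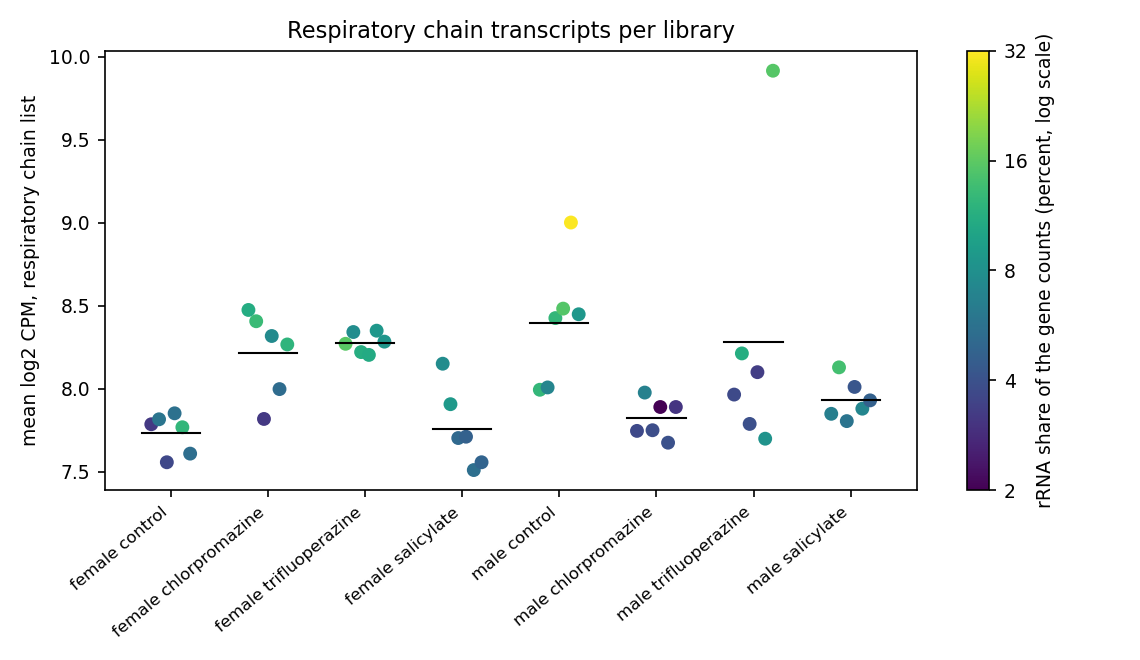
Mean log2 CPM of the respiratory chain list in each library (points) by group, coloured by the share of rRNA reads. Means are 7.73 in female and 8.39 in male controls.

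Mean log2 CPM of the respiratory chain list was 7.73 ± 0.12 in female controls, 8.21 ± 0.25 under chlorpromazine and 8.28 ± 0.06 under trifluoperazine, and in males 8.39 ± 0.37, 7.82 ± 0.12 and 8.28 ± 0.82. Within groups, over the 48 libraries, it correlated with the share of rRNA reads (Pearson r = 0.559, permutation adjusted p = 2.4e-04, Spearman rho = 0.484, permutation adjusted p = 0.00201, r = 0.448 without male control replicate 5 and male trifluoperazine replicate 6). It also correlated with the spike-in share (r = 0.574, permutation adjusted p = 4.2e-04, rho = 0.485, permutation adjusted p = 6.6e-04, r = 0.346 without male trifluoperazine replicate 6 and female salicylate replicate 1). The third relation tested, rRNA against spike-in share, gave r = 0.281 (permutation adjusted p = 0.0869) and rho = 0.237 (permutation adjusted p = 0.111), with r = 0.167 without the 2 libraries left out of the first relation. By group, r of the list with the log2 rRNA share ran from -0.571 in female trifluoperazine to 0.920 in female chlorpromazine. Labels gave no sequencing batch usable within groups.

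The same mass of ERCC spike-in RNA went into 30 ng of total RNA for each library, so its share of the counts was compared between groups. Female medians were 0.436% under chlorpromazine and 0.378% under trifluoperazine against 0.193% in controls, higher on 6 of 6 days for both (mean log2 difference 1.06 ± 0.28 SD for each). Under salicylate the female median was 0.30%, higher on 5 of 6 days. Male medians were 2.37% under chlorpromazine, 2.34% under trifluoperazine and 1.59% under salicylate against 0.873% in controls, each higher on 6 of 6 days, and the mean log2 differences were 1.38, 1.89 and 0.81. In a two-sided exact permutation test without pairing, the adjusted p was 0.408, 0.408 and 0.485 in females and 0.0779, 0.0779 and 0.113 in males. With days as blocks, an exact sign-flip permutation test gave an adjusted p = 0.0375 for all but female salicylate (0.0625), and the smallest raw p that 6 days allow is 0.0312. Scaled to spike-ins in place of TMM, the median gene shifted by -1.16 in chlorpromazine-fed and -1.08 in trifluoperazine-fed females, by -0.90 and -0.92 in males, by -0.44 and -0.63 under salicylate in females and males, and by 1.81 between control sexes. All fold changes above are relative to the TMM scale. On the spike-in scale 33 of the 67 results named in chlorpromazine-fed and 32 of the 55 in trifluoperazine-fed females turned from a rise to a fall, as did Gfat2, TBC1D23 and l(1)G0320 over both sexes under chlorpromazine, and msl-2 turned between the control sexes. None of the 146 results named within a sex passed the threshold on that scale. Of the 59 others 20 kept their side of it, uncalled ones included. Spike-in pool and sex were nearly the same split, so the shift between control sexes is not read as a difference in RNA.

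**Figure D5:**
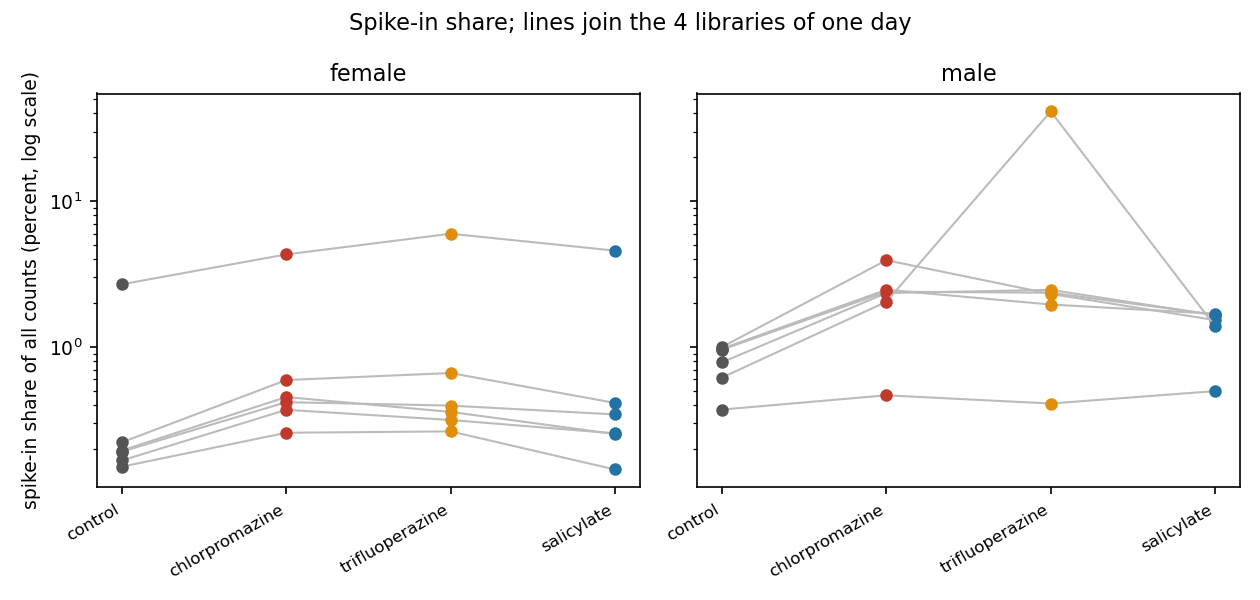
Spike-in share of all counts (percent, log scale) by treatment in females and males, where lines join the 4 libraries of the same day. Drug libraries lie above the control of their day on 6 of 6 days in each panel except for salicylate in females, at 5 of 6.

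Marker transcripts of other tissues, summed per library, gave no difference between a drug and its control that passed an exact permutation test over the 6 comparisons of each tissue. Gut enzymes had a mean of 1689 ± 3027 CPM in chlorpromazine-fed and 427 ± 552 in control females, and 3855 ± 5749 against 190 ± 12.3 in males (adjusted p = 0.312 and 0.234). Muscle, retina, fat body and cuticle sums had an adjusted p of 0.338 or more.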

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

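Tests here chosen only after the result was seen were the rRNA covariate, length trend removal, salicylate as reference and splits exchanging a female day. So were those of a single spike-in library, the spike-in pool and the polyadenylated RNA content.

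The responses to the phenothiazines differed between the sexes by the interaction test, for 3319 genes under chlorpromazine and 1916 under trifluoperazine. As female minus male log2 change, Mpcp2 differed by 1.1, CG13631 by 1.5, Eno by 0.84, Nt5a by 0.95, Ars2 by -1.27, CG42724 by -1.70, Pitslre by -1.61 and Socs16D by -1.03 under chlorpromazine. Under trifluoperazine Mpcp2 differed by 1.24, CG7430 by 0.84, eIF3l by 0.98, Gapdh2 by 1.07, Ars2 by -1.09, SF1 by -1.21, Pitslre by -1.57 and Xe7 by -1.66.

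For this first pattern, a trend on exon length as the whole cause is argued against for trifluoperazine, where 1522 genes passed after its removal, and stays open for chlorpromazine, where 1153 of 3319 did. The rRNA share of the libraries cannot be told apart from the drug effect, since 345 genes passed with it as a covariate for chlorpromazine and 1238 for trifluoperazine (939 of 1939 with the block) and it moved with the groups. Male control libraries that stand apart from the other male libraries are a candidate explanation, as 0 genes were called by edgeR in males for chlorpromazine against salicylate (311 at unadjusted p under 0.05) and 0 for trifluoperazine against salicylate (1595), without DESeq2 having been run on these contrasts, although a response shared by the 3 drugs in males would give 0 as well. Male controls 3 to 6 stand apart from 1 and 2 for Mpcp2 (2676 to 2999 against 1739 and 1828 CPM). So they do for CG42724 (21.8 to 31.1 against 46.2 and 48.9), Xe7 (55.9 to 69.1 against 114 and 118), Eno, Pitslre and Socs16D. Replicates 1 and 2 lie near the drug-fed males there. For Ars2, CG13631 and Nt5a all chlorpromazine males lie beyond all 6 controls. A response that truly differs between the sexes stays open too, with 783 and 560 genes called for the sex difference with salicylate as the reference, or 1831 and 844 without male trifluoperazine replicate 6.

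The second pattern is the set of gut-like genes among the 68 rises under chlorpromazine over both sexes. Gut tissue carried over in dissection may explain it, since 79.4% of the rises had their highest female control value in female control replicate 5, the gut-rich control, and gut enzymes are a list written beforehand. Induction by chlorpromazine in most libraries was met by 10 of 68 rises, those higher in at least 10 of 12 pairs. That pairs without a count have no sign, which lowers this number, was set after results were seen. Neither test settles it, because chlorpromazine-fed flies hold 4 of the 7 gut-rich libraries.

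The third pattern is the higher spike-in share of the drug groups. A single extreme library as the whole cause is argued against by the 5 comparisons that do not hold male trifluoperazine replicate 6, where the lowest mean same-day log2 difference was 0.57 (SD 0.365, higher on 5 of 6 days). In males on trifluoperazine it cannot be told apart from a wider rise, since without that library the mean same-day log2 difference went from 1.89 to 1.06 (SD 0.565, higher on 5 of 5 days). The spike-in pool is argued against by a ratio of medians of 1.95 as the lower of the 2 female phenothiazine ratios when only spike-ins of similar abundance in both pools were used. Less polyadenylated RNA per unit of total RNA in drug-fed flies cannot be told apart from other causes, the mean rRNA share being higher in 3 of the 6 drug groups only.

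Single libraries lay far from their group, by gap over range, for 26 of the 80 combinations of 10 measures and 8 groups. Chance gives about 1 in 20 for normal values, which these need not be. Gene counts were far above the others in female salicylate replicate 6 (14290000), male salicylate replicate 1 (11111000) and male trifluoperazine replicate 1 (12988000). The spike-in share was 4.32, 2.69, 4.58 and 5.99% in replicate 1 of female chlorpromazine, control, salicylate and trifluoperazine. It was 0.499% in male salicylate replicate 1 and 41.3% in male trifluoperazine replicate 6. Per the labels, spike-in pool 78B went into female replicate 1 and male replicates 2 to 6, and pool 78A into the others. The 4 treatments of a day share a pool, and replicate 1 differs from its group in pool. The rRNA share was 12.4% in female control replicate 5, 31.3% in male control replicate 5 and 13.9% in male salicylate replicate 2, and 12314 genes were detected in male chlorpromazine replicate 6.

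Gut enzyme transcripts summed to 7814 CPM in female chlorpromazine replicate 3, 1553 in female control replicate 5, 631 in female trifluoperazine replicate 6, 1303 in male salicylate replicate 6 and 6720 in male trifluoperazine replicate 1. Muscle markers summed to 1942 CPM in female trifluoperazine replicate 5 and 1805 in male chlorpromazine replicate 6. Retina markers summed to 8668 CPM in female chlorpromazine replicate 5, 5599 in female salicylate replicate 6 and 7154 in male salicylate replicate 2. Fat body markers summed to 56540 CPM in female control replicate 2, heat shock genes to 29628 CPM in female control replicate 4 and cuticle genes to 1199 CPM in female trifluoperazine replicate 5.

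Other splits of the same libraries were counted for each set of calls, with the real split among the 100. Chance can be excluded for chlorpromazine in females, where 1 of the 100 splits gave as many genes (2035, with 74 the highest other). It can also be excluded in males (1, 544 against 204) and for trifluoperazine in females (1, 1838 against 534). The same holds for the sex difference under chlorpromazine (1, 3319 against 278). For the sex difference under trifluoperazine the share of splits was under 0.05 (2, 1916 against 3138). Another split called more genes there than the real one, so chance is not firmly excluded. For the control sexes 2 of the 100 gave as many (1246 against 1365), but so did 3 of the 32 that part as many day pairs, and chance is not excluded there. Chance cannot be excluded for chlorpromazine over both sexes (8, 92 against 500), trifluoperazine over both sexes (10, 2 against 2476) and in males (16, 62 against 2778), or salicylate in males (12, 2 against 771). Nor can it be excluded where edgeR called 0 genes, so that all 100 splits gave as many. These were salicylate over both sexes (highest other 260, DESeq2 12), in females (4, DESeq2 20) and for its sex difference (74, DESeq2 56), and chlorpromazine against trifluoperazine (1394, DESeq2 13). For the lists 29 of 60 splits gave as many for chlorpromazine (13 against 22), 15 for trifluoperazine (14 against 21) and 40 for salicylate (11 against 24), so chance cannot be excluded.

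Splits that part as many day pairs as the real one numbered 40 for each drug. As many genes were called in 1 of them for chlorpromazine in females (highest other 1745), in males (326) and for its sex difference (2696), and for the sex difference under trifluoperazine (1400). As many were called in 2 for trifluoperazine in females (1853), 6 for chlorpromazine over both sexes (256), 10 for trifluoperazine over both sexes (2108), 12 for trifluoperazine in males (2468) and 5 for salicylate in males (760). The highest others for both phenothiazines in females exchanged 0 female days and 1 male day, so they hold the real female groups and are no comparison for the female calls. Among splits that exchange at least 1 female day, 1 of 39 gave as many for chlorpromazine (highest other 405) and 1 of 37 for trifluoperazine (479). For the control sexes the highest other (1365) exchanged 2 days, and the block gave 1319.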

How the results depend on the processing

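Here the rRNA covariate, length trend removal and spike-ins picked by pool ratio were chosen only after the result was seen. So were omissions of single, gut-rich or spike-rich libraries.

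With spike-in library sizes 12 genes were called for chlorpromazine, 153 for trifluoperazine and 2 for salicylate over both sexes, 4 and 5 for chlorpromazine, 2 and 29 for trifluoperazine and 3 and 0 for salicylate in females and males, 0 for the sex difference under each phenothiazine and 697 between the control sexes. Under each drug none of these calls was a rise except 1 of the 29, 0 of those over both sexes were shared with the TMM scale, and 688 of the 697 were higher in females. The spike-in share varied between replicates of a group, and this variation enters every gene under that scaling. Without a filter 0 genes were called for chlorpromazine, 0 for trifluoperazine, 155 and 11 for them in males, 0 for salicylate in males and 815 between the control sexes, with more genes tested. With relative log expression factors 1 gene was called for trifluoperazine over both sexes and 0 for salicylate in males, and with at least 5 CPM in 6 libraries 4 and 0.

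With the replicate block 9 genes were called for chlorpromazine and 6 for trifluoperazine over both sexes, and their overlap was 0. Under the block the spike-in share passed the threshold for chlorpromazine and trifluoperazine in females (log2 1.06 and 1.06) and for chlorpromazine, trifluoperazine and salicylate in males (1.38, 1.89 and 0.81). With spike-ins of a pool ratio near 1 it passed for trifluoperazine and salicylate in males (2.49 and 1.17). With the controls split by replicate number, the overlap over both sexes was 0 with controls 1 to 3 for the first drug, where 18 and 0 genes were called so that no overlap was possible, and 0 with controls 4 to 6, where 9 and 37 were called (correlation 0.551 and 0.606). In fits of only the groups compared, 0 genes were called for chlorpromazine, 0 for trifluoperazine and 0 for trifluoperazine and salicylate in males, and 1199 for the sex difference under trifluoperazine, with fewer samples.

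By the DESeq2 Wald test 220 genes were called for chlorpromazine, 27 for trifluoperazine and 12 for salicylate over both sexes, 846 for chlorpromazine, 140 for trifluoperazine and 26 for salicylate in males, 20 for salicylate in females, 56 for its sex difference and 13 between the phenothiazines. Camera with an estimated correlation called 0 lists for each of the 3 drugs, and fry called 0 for chlorpromazine, 1 for trifluoperazine and 0 for salicylate.

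Without the gut-rich and spike-rich libraries 0 genes were called for chlorpromazine and 1 for trifluoperazine over both sexes, 0 for trifluoperazine and 0 for salicylate in males, 3269 for the sex difference under trifluoperazine and 1945 between the control sexes, and 8 lists for chlorpromazine and 7 for salicylate. With the rRNA covariate 13 genes were called for chlorpromazine over both sexes, 0 for it in males, 1089 and 387 for trifluoperazine in females and males, 0 for salicylate in males, 345 and 1238 for the sex differences under chlorpromazine and trifluoperazine, and 729 between the control sexes. With block and rRNA covariate these were 5, 0, 1024, 4, 0, 157, 939 and 340, with 7 for trifluoperazine over both sexes. In that fit GstD3 under chlorpromazine in males reversed to 0.00 (0.003 before rounding).

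After removal of the length trend 151 genes were called for chlorpromazine over both sexes, 974 and 122 for it in females and males, 0 for salicylate in males and 1153 for the sex difference under chlorpromazine. With the block as well these were 57, 1025, 133, 0 and 1210, with 8 for trifluoperazine over both sexes and 106 for it in males. The cause of the changes above, beyond those with fewer samples or more genes tested, was not tested.

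With each library or each replicate number left out in turn, counts ranged from 0 to 199 for chlorpromazine, 0 to 11 for trifluoperazine and 0 to 1 for salicylate over both sexes. They ranged from 795 to 3135 and 2 to 1806 for chlorpromazine in females and males, 958 to 2627 and 0 to 251 for trifluoperazine, and 0 to 246 for salicylate in males. For the sex differences they ranged from 2051 to 4216 under chlorpromazine, 816 to 3184 under trifluoperazine and 0 to 7 under salicylate, between the phenothiazines from 0 to 161 and between the control sexes from 280 to 2222. Lists, tested without each replicate number, ranged from 10 to 18 for chlorpromazine, 11 to 15 for trifluoperazine and 9 to 13 for salicylate. Of single libraries only male trifluoperazine replicate 6, female control replicate 4 and male control replicate 5 were left out for lists, which gave 13, 16 and 17, then 14, 16 and 14, and 11, 12 and 9. The fold change of Dop1R2 under chlorpromazine over both sexes, which did not pass the test, ranged from -0.17 to 0.032 and was above 0 without replicate 2.

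The 59 results named by the rule fixed beforehand had 1057 values under 18 alternatives, of which 817 kept direction and side of the threshold, 239 kept direction but not the threshold and 1 reversed. For the 146 named within a sex the numbers were 2617, 2243, 373 and 1. The spike-in scale is not among the 18. List tests within a sex were not rerun under other scalings.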

Other observations

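Tests in this part that use salicylate as a reference were chosen only after the result was seen.

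Of 24 barcodes, chlorpromazine and salicylate libraries of the same sex and day shared 12, and control and trifluoperazine the other 12. If partners were read in separate lanes, drug and lane cannot be told apart between them. Between females and males 2681 genes differed under chlorpromazine, 1959 under trifluoperazine and 97 under salicylate, beside 1246 in controls. Without male trifluoperazine replicate 6 these were 3818, 2346, 163 and 2222. Against salicylate in females, 2137 genes were called for chlorpromazine and 1911 for trifluoperazine, or 3092 and 2738 without that library.

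Fold changes of chlorpromazine and salicylate over both sexes correlated across genes by 0.423, those of trifluoperazine and salicylate by 0.215. Independent unchanged genes simulated against the same controls gave 0.178 and 0.184. With the controls divided by day between the 2 drugs the correlations were 0.117 and 0.716 for chlorpromazine and -0.129 and 0.428 for trifluoperazine, and with the block 0.293 and 0.0921. In males the correlations were 0.818 and 0.726 against 0.108 and 0.113 simulated, and with divided controls 0.606 and 0.624 for chlorpromazine and 0.448 and 0.543 for trifluoperazine.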
